A study of Caenorhabditis elegans with 2 samples.

How the data were processed

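Chromatin from whole L1 larvae of strain OP228, in which eGFP-tagged NHR-237 is expressed from an integrated transgene, was immunoprecipitated and sequenced in 2 biological replicates, per the labels, which give the replicate numbers and a DNA size range of 150 to 350 bp. The labels describe the target as the eGFP fusion and name the factor itself in the antibody field, so which of them the antibody recognised was not settled here. The labels name a possible control experiment, which was not analysed here. The number of reads per sample is unknown, and no interval given here covers it.

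The deposited files are 8 peak lists in narrowPeak format, 4 on ce10 and 4 on ce11. Per the readme files deposited with them, each replicate list was derived from that replicate's alignment and a control alignment, the pooled list from both replicates' alignments and a control alignment, and the IDR list from the pooled and both replicate lists. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The signal value of each region is a score from the authors' peak caller, with a scale that is not stated, so it was used only to rank and describe regions within its own list. The deposited q-value column is −log10 of q by the narrowPeak format, reached 2.93 in the ce11 IDR list, and was not used in any test. The deposited p-value column is unassigned for every region. A further deposited column gives the summit, which lay at the middle of the region in 97.01% of IDR peaks. Regions were nearly all of 1 width per list (364 bp for the pooled and IDR lists, 360 bp for replicate 1 and 380 bp for replicate 2), and widths were not analysed further. Most of the 15 strongest IDR peaks were among the few narrower regions. The unthresholded lists also hold weak regions with q near 1, and chance overlap with them is high, for which reason shares of overlapping peaks are given beside random placements.

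Genes came from the Ensembl release 115 annotation of WBcel235, which has the coordinates of ce11, and bases from the RefSeq sequence of the same assembly. All ce11 regions lay on the 6 nuclear chromosomes within their lengths. No coordinates were converted between builds. For placements on ce10 the highest region end of each chromosome stood in for its length.

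Overlap was at least 1 bp. Shares in replicates, annotation classes and distances were compared with 1000 random placements within chromosomes, and chromosome shares with 1000 placements over the nuclear genome (a permutation of peak positions, two-sided, smallest p 0.001). Summits were classed in the order promoter, 5′ UTR, coding exon, 3′ UTR, intron, intergenic, where a promoter is 1000 bp upstream to 200 bp downstream of any start site of a protein-coding gene. Gene lists were fixed by gene name before the data were examined. They were nuclear hormone receptors, ribosomal proteins, histones, collagens, vitellogenins, V-ATPase, proteasome, translation factors, aminoacyl-tRNA synthetases, chaperones, mitochondrial respiratory chain, cytochromes P450, UDP-glucuronosyltransferases, glutathione S-transferases, ABC transporters, lipid metabolism, C-type lectins, F-box, chemoreceptors, neuropeptides and insulins, homeobox, bHLH, bZIP, forkhead, GATA factors, splicing, autophagy, heterochronic, insulin signalling, cell cycle and sperm proteins, with markers of 7 tissues. The symbols opt-2 and mir-228 matched no protein-coding gene. Lists were tested by Fisher exact tests (two-sided, conditional odds ratio), noncoding RNA genes within 250 bp of a summit by random placements, and motifs within 50 bp of the summit by exact McNemar tests against windows centred 300 bp away. Benjamini-Hochberg adjustment was made within each of these families, with a threshold of 0.05. Flank shares of motifs are means of the windows on both sides, while each McNemar test used 1 side per peak, drawn at random. Shuffled windows were treated in the same way. Shares have 95% Clopper-Pearson intervals, which cover counting error only.

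The rule for named genes was also fixed before the data were examined. It takes nhr-237 and unc-119, the genes at the 15 IDR peaks of highest signal (start site within 2 kb, and both genes where 2 promoters hold the summit) with up to 3 of those peaks without a gene by position, the 4 bound members of highest signal in each list bound more often, and the 2 highest in each other list. The genes lin-23, srx-125, fbxa-37, fbxb-85, fbxc-19, ears-2, fars-1, atg-9, epg-7, col-71, his-68, nlp-34 and haf-3 complete short lists and were added after their values were seen. One bound member of the chemoreceptor list is not reported here. So were Y41G9A.17 and cept-2, which hold a named summit.

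Alternatives were other overlap rules, the ce10 lists, other promoter windows, distances and motif windows, the 485 IDR peaks of highest signal, nearest genes only, a background of genes with regions in both replicates, shuffled bases as motif control, and leaving out each replicate by using the 970 strongest regions of the other. Placements matched on GC content were added after the data were seen. On simulated promoters with 5% bound, the list test recovered translation factors bound at 30% in 19 of 20 simulations, cell cycle genes at 20% in 11, chemoreceptors at 0.5% in 20 and F-box genes at 1.5% in 7, and called 9 of 680 unchanged lists. Of 60 pairs of unrelated simulated lists of 970 regions, 3 had an overlap p under 0.05. The test within GC strata called 0 of 90 lists simulated without an effect and recovered chaperones bound at 30% in 10 of 10. Both simulations of lists drew each gene independently, so their rates do not cover neighbouring genes that share a promoter region. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9 were used.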

Results

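NHR-237 is a nuclear hormone receptor of Caenorhabditis elegans, one of a large family of DNA-binding proteins of which some are controlled by small lipid-like ligands. Its binding across the genome was measured by ChIP-seq in whole first-stage (L1) larvae of pooled sex. The strain, OP228, carries an integrated transgene that expresses the factor fused to eGFP in an unc-119 mutant background. There was 1 group of 2 biological replicates. The measurements are peak lists, in which each region has a signal value given by the authors' peak caller. The number of reads behind them is unknown, so no interval below covers sequencing depth. On the ce11 build the replicate 1 list held 21745 regions, the replicate 2 list 25720, the list from both replicates pooled 7699, and the list that passed the authors' irreproducible discovery rate (IDR) threshold 970. These 970 IDR peaks were also the 970 pooled regions of highest signal, from 52.6 to 419 with a median of 74.0. The usual peak was 364 bp wide, and 29 were narrower, down to 95 bp. The same reads on the older ce10 build gave 1007 IDR peaks. All positions below are on ce11, counted from 1. No untagged or input sample was analysed here. Tests compare peaks or genes within these lists, so the spread between replicates enters through the comparison of both lists and by leaving out each replicate in turn.

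The first question was whether both replicates gave the same regions. It was answered at equal list length and without the IDR selection. Of the 970 regions of highest signal in replicate 1, 622 (64.1%, 95% exact CI 61.0 to 67.1) were among the 970 highest of replicate 2, and 629 (64.8%, 61.7 to 67.9) the other way. Random placement gave 0.714% and 0.718%. Each permutation p was 0.001, the smallest that 1000 placements can give (two-sided). Of the IDR peaks, 969 (99.9%, against 14.9% at random) overlapped a region of the replicate 1 list and 967 (99.7%, against 17.8%) one of the replicate 2 list. The IDR list was derived from these lists, so that overlap was largely set by its making and does not measure how alike the replicates were. The region upstream of rpl-3 ranked 1 and the region upstream of cdc-48.1 ranked 2 in both replicates. Across the 966 IDR peaks with a region in both lists, the replicate signals had a Spearman rho of 0.53 and a Pearson r of 0.62 on the log2 scale (permutation p = 1e-05 for each, the smallest that 100000 resamples can give). This is a correlation across peaks, which are not independent replicates and were chosen on the pooled signal. Among the 970 strongest regions, 39 of replicate 1 and 30 of replicate 2 had no overlapping region in the other list. The strongest of these ranked 245 and 282.

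**Figure D1:**
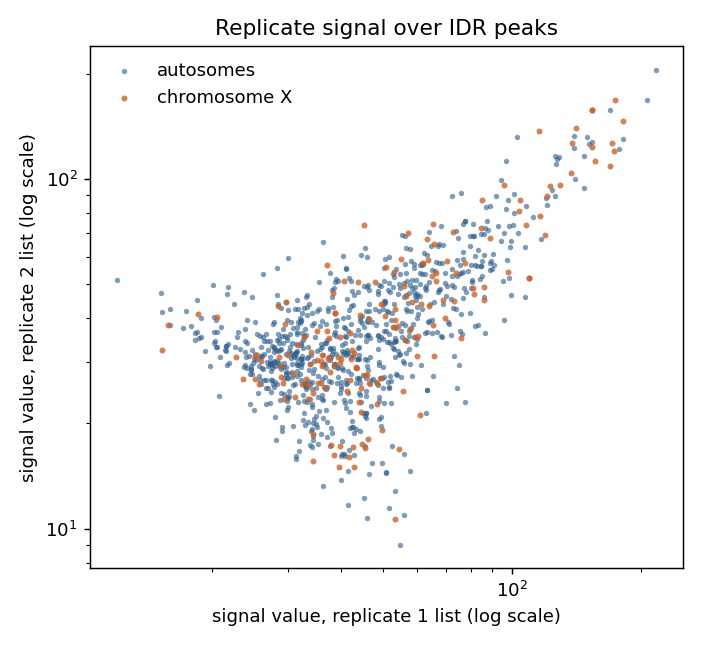
Signal value of each IDR peak in the replicate 1 list (horizontal, log scale) and the replicate 2 list (vertical, log scale), for the 966 peaks with a region in both, with autosomes and chromosome X in different colours. The highest signals lie together in both replicates, up to 216 and 205 upstream of rpl-3, while weaker peaks scatter more (Spearman rho 0.53).

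The IDR peaks lay mainly just upstream of genes. Of the 970 summits, 669 (69.0%, 95% exact CI 66.0 to 71.9) lay in a promoter, counted as 1000 bp upstream to 200 bp downstream of an annotated start site of a protein-coding gene. Random placement gave 25.8%, so promoters held 2.67 times as many (two-sided permutation p = 0.001, the smallest that 1000 placements can give). Coding exons outside promoters held 3 summits (0.309%, against 18.9% at random), introns 94 (9.69% against 28.0%) and 3′ UTRs 1 (0.103% against 2.36%). The permutation p was 0.001 for each. Intergenic sequence held 200 (20.6% against 24.5%, permutation p = 0.005), and 5′ UTRs held 3 (0.309% against 0.419%, permutation p = 0.64). The median distance from a summit to the nearest start site of a protein-coding gene was 311 bp, with quartiles of 160 and 1187 bp, against 1338 bp at random (permutation p = 0.001). Summits were upstream of that start site in 795 cases (82.0%, 79.4 to 84.3), and 155 (15.98%) were more than 2 kb from any such site. With start sites of all annotated genes the median distance was 209 bp and the upper quartile 587 bp.

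**Figure D2:**
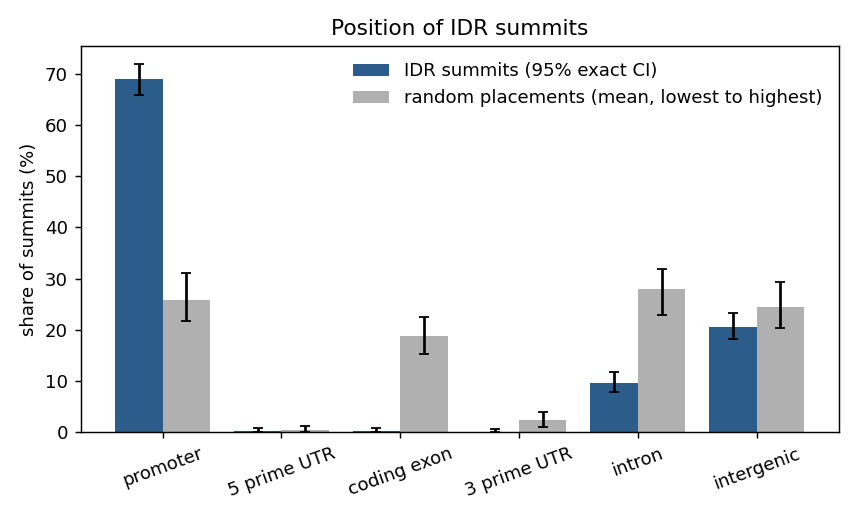
Share of the 970 IDR summits in each annotation class (%, bars with 95% exact confidence intervals) beside the mean of 1000 random placements (bars from the lowest to the highest placement). Promoters held 69.0% of summits against 25.8% at random, and coding exons 0.309% against 18.9%.

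The strongest peak lay on chromosome III from 3867462 to 3867698, with its summit in intergenic sequence 284 bp upstream of rpl-3, which encodes a protein of the large ribosomal subunit. Its signal was 419, with 216 in replicate 1 and 205 in replicate 2. The next, on chromosome II from 10563475 to 10563674, was 179 bp upstream of cdc-48.1, a homolog of the p97 ATPase that unfolds ubiquitinated proteins (signal 376, replicates 206 and 169). Of the 15 strongest peaks, 8 lay in the promoter of a protein-coding gene. Besides those of rpl-3, cdc-48.1 and nspc-17, 3 of these regions were upstream of other ribosomal protein genes. One on chromosome IV, 4749968 to 4750174, was 287 bp upstream of rpl-20 and 175 bp upstream of Y17G9B.5 (signal 327). One on chromosome III, 7854614 to 7854795, was 448 bp upstream of rpl-35 (285). One on chromosome III, 5679065 to 5679210, was 158 bp upstream of rps-12 and 135 bp upstream of ska-3, and within 250 bp of a snoRNA gene (278). The region on chromosome II from 8561358 to 8561520 lay between iff-2, which encodes the translation factor eIF5A, and F54C9.14 (312), and that on chromosome III from 10759132 to 10759327 between tasp-1 and K01G5.10 (306). Chromosome X held 7 of the 15. They included a region 1780 bp upstream of F20B6.9 (4209184 to 4209364, signal 329), a region 731 bp upstream of nspc-17 (14525801 to 14526023, signal 288) and a region 1760 bp downstream of the start of F19H6.5 (12363107 to 12363224, signal 276). Of the 15, 5 were more than 2 kb from a start site of a protein-coding gene, and 4 of those were on X. The strongest were at X 9465790 to 9465920 (intergenic, signal 344), X 2997022 to 2997177 (in an intron of Y41G9A.17, 316) and X 16682043 to 16682183 (intergenic, 296).

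Genes of ribosomal proteins, translation factors, chaperones, the mitochondrial respiratory chain and the V-ATPase were bound at their promoters more often than other genes. A promoter with an IDR summit was found for 930 of 19973 protein-coding genes (4.66%). Of 81 ribosomal protein genes, 56 were bound (69.1%, 95% exact CI 57.9 to 78.9; odds ratio 48.7, 95% CI 29.7 to 81.9; adjusted Fisher p = 3.40e-54), led by rpl-3, rpl-20, rpl-35 and rps-12. Translation factors had 12 of 39 bound (30.8%, odds ratio 9.20, 4.23 to 18.9, adjusted Fisher p = 8.97e-07). The strongest peaks of this list were those of iff-2 (signal 312), of the elongation factor genes eef-1A.1 (242, at III 6972035 to 6972188) and eef-1A.2 (174), and of eef-1G (141). Chaperones had 18 of 59 (30.5%, odds ratio 9.14, 4.92 to 16.4, adjusted Fisher p = 1.21e-09). Among them were hsp-110 (248.7), hsp-90 (202, with the summit in an intron of the gene 337 bp upstream of its nearest start site), the cytosolic chaperonin gene cct-1 (186) and the mitochondrial chaperonin gene hsp-60 (164). The respiratory chain of mitochondria had 12 of 39 (30.8%, odds ratio 9.20, 4.23 to 18.9, adjusted Fisher p = 8.97e-07), led by the cytochrome c oxidase subunit genes cox-5A (247), cox-6B (162) and cox-5B (137) and the ATP synthase gene atp-1 (144). The V-ATPase, which acidifies organelles, had 7 of 20 (35.0%, odds ratio 11.1, 3.74 to 30.01, adjusted Fisher p = 8.91e-05), led by vha-8 (163), vha-12 (153), vha-1 (124) and vha-13 (81.2, with its summit in an exon of the neighbouring gene cept-2).

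Splicing genes, the proteasome, bZIP transcription factors and cell cycle genes were also bound more often. The splicing and bZIP calls were kept in all 7 alternatives, the proteasome and cell cycle calls in 5 of 7. Splicing had 10 of 38 (26.3%, odds ratio 7.38, 3.19 to 15.7, adjusted Fisher p = 4.15e-05), led by the Sm protein gene snr-4 (106), the SR protein genes rsp-6 (105) and rsp-3 (87.6), and prp-19 (105). The proteasome had 7 of 33 (21.2%, odds ratio 5.55, 2.03 to 13.2, adjusted Fisher p = 0.0026). Its strongest peak, upstream of rpn-3 at III 8447110 to 8447204 (248.7), is the same region as that of hsp-110, and the next were those of rpt-2 (70.2), rpn-9 (67.1) and rpn-11 (65.9). The bZIP factors had 8 of 25 (32.0%, odds ratio 9.71, 3.62 to 23.8, adjusted Fisher p = 6.20e-05). They included jun-1 (157), the pathogen response factor zip-2 (142), the oxidative stress factor skn-1 (118, in an intron) and the C/EBP factor cebp-1 (112). Cell cycle genes had 5 of 25 (odds ratio 5.14, 1.504 to 14.2, adjusted Fisher p = 0.017). These were the E2F gene efl-1 (134), the retinoblastoma gene lin-35 (109), cdk-7 (99.4), cdk-5 (77.8), which is known for its part in neurons and not in division, and lin-23.

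Chemoreceptors and C-type lectins were bound less often, and so were F-box genes against all other protein-coding genes, though not under most of the alternatives. Of 1364 genes in the chemoreceptor list 4 were bound (0.293%, odds ratio 0.0562, 0.0152 to 0.145, adjusted Fisher p = 1.86e-22). They included sri-5 (signal 115), srh-16 (67.0) and srx-125. The list was made by a name pattern, which also takes in some genes that are not receptors. None of 240 C-type lectin genes was bound (exact upper limit 1.53%, adjusted Fisher p = 8.38e-05). F-box genes had 5 of 322 (1.55%, odds ratio 0.319, 0.103 to 0.756, adjusted Fisher p = 0.016), namely fbxb-58 (219), fbxa-90 (134), fbxa-37, fbxb-85 and fbxc-19. The F-box call was kept in 3 of 7 alternatives, while the chemoreceptor and C-type lectin calls were kept in all 7. The fbxa-90 peak is the one that also lies 166 bp upstream of efl-1.

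**Figure D3:**
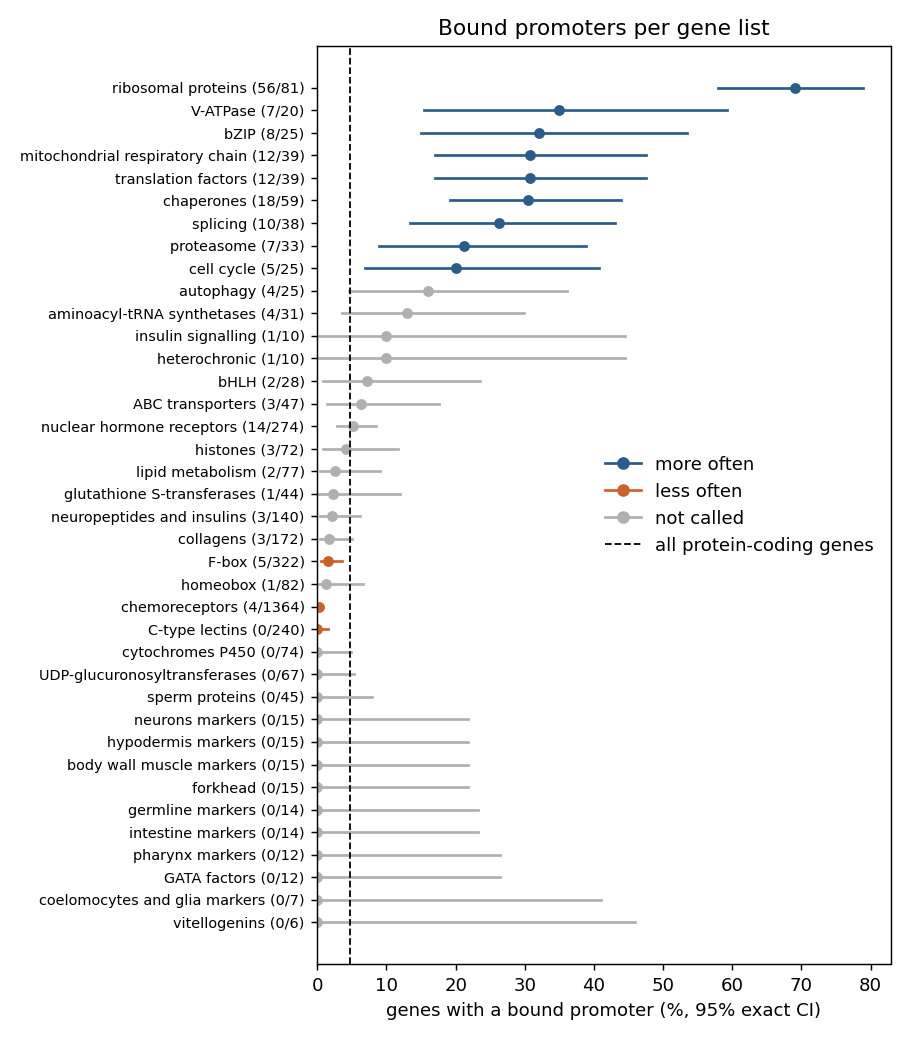
Share of genes with a bound promoter in each of the 38 lists (%, points with 95% exact confidence intervals; bound and total genes in brackets), with the share of all protein-coding genes, 4.66%, as a dashed line. Ribosomal protein genes stand highest at 69.1%, and the chemoreceptor, C-type lectin and F-box lists lie below the line.

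The other 26 lists were not called. The factor's own family, the nuclear hormone receptors, had 14 of 274 bound (5.11%, odds ratio 1.10, 0.593 to 1.90, adjusted Fisher p = 0.97), with nhr-142 (signal 89.1) and nhr-48 (76.6) strongest. Aminoacyl-tRNA synthetases had 4 of 31 (odds ratio 3.04, adjusted Fisher p = 0.14; kars-1 81.4, mars-1 75.6, ears-2, fars-1) and autophagy genes 4 of 25 (3.91, adjusted Fisher p = 0.079; lgg-1 128, lgg-2 127, atg-9, epg-7). Collagens had 3 of 172 (0.361, adjusted Fisher p = 0.16; col-38 108, col-2 75.2, col-71) and histones 3 of 72 (0.890, adjusted Fisher p = 1; his-37 244, his-67 79.0, his-68). The col-38 region is the one that also lies 390 bp upstream of the ribosomal protein gene rpl-5, and his-67 and his-68 share a region. Neuropeptide and insulin genes had 3 of 140 (ins-39 188, nlp-31 56.6, nlp-34), ABC transporters 3 of 47 (mrp-2 129, wht-3 77.4, haf-3) and lipid metabolism 2 of 77 (ech-5 74.8, fat-3 53.4). The bHLH factors had 2 of 28 (hlh-11 67.4, hlh-30 59.1), homeobox genes 1 of 82 (ceh-38 144) and glutathione S-transferases 1 of 44 (gst-5 97.7). Heterochronic genes had 1 of 10 (lin-28 87.3) and insulin signalling 1 of 10 (akt-2 75.9). No promoter was bound among 74 cytochrome P450 genes (adjusted Fisher p = 0.14), 67 UDP-glucuronosyltransferases (0.17), 45 sperm protein genes, 15 forkhead genes, 12 GATA factor genes and 6 vitellogenins. These lists are too small for 0 bound genes, the lowest count possible, to pass the test. Their exact upper limits ran from 4.86% for cytochrome P450 genes to 45.9% for vitellogenins.

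No tissue marker had a bound promoter. The 7 marker lists held 14 genes of intestine, 15 of body wall muscle, 15 of hypodermis, 15 of neurons, 12 of pharynx, 14 of germline and 7 of coelomocytes and glia. Together these are 92 genes with 0 bound, where the share over all genes would give 4.28. The adjusted Fisher p was 1 for each list, but lists of 7 to 15 genes are too small for 0 bound genes to pass the test. Taken as one set, they gave a Fisher exact p of 0.023 (exact upper limit 3.93%). That set was formed after each list had been seen at 0, so this p is not independent evidence.

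Lists were tested by a two-sided Fisher exact test with Benjamini-Hochberg adjustment over all 38, and neighbouring genes that share a promoter region are not independent. Against only the 4313 genes whose promoter held a region in both replicates' unthresholded lists, 7 lists were bound more often and 2 less often. The ribosomal odds ratio was then 13.6 (adjusted Fisher p = 3.07e-23), while the proteasome (1.83, adjusted Fisher p = 0.33), cell cycle (4.59, adjusted Fisher p = 0.064) and F-box lists (0.730, adjusted Fisher p = 0.85) were no longer called. With each region given to its nearest gene alone, the ribosomal odds ratio was 23.4. Without replicate 1, the 970 strongest regions of replicate 2 no longer gave a call for the cell cycle (3.94, adjusted Fisher p = 0.078) or F-box lists (0.387, adjusted Fisher p = 0.052). Without replicate 2, the aminoacyl-tRNA synthetases were called as bound more often (4.13, adjusted Fisher p = 0.036). In the 485 IDR peaks of highest signal the proteasome odds ratio was 1.19 (adjusted Fisher p = 0.95) and that of F-box genes 0.598 (adjusted Fisher p = 0.70).

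Genes of small noncoding RNAs lay near summits more often than in random placements within chromosomes. These placements do not allow for the 69.0% of summits in promoters of protein-coding genes, against 25.8% at random. Whether the excess goes beyond nearness to gene starts was not tested. Nor was signal that any ChIP may give at such genes, since no untagged control was analysed here. Within 250 bp of a summit were 32 of 612 tRNA genes (5.23%, against 3.41 genes at random, 9.39-fold), 22 of 346 snoRNA genes (6.36%, against 2.20, 10.02-fold) and 8 of 129 snRNA genes (6.20%, against 0.762, 10.5-fold). The adjusted permutation p was 0.0017 for each, over 5 classes, from raw values of 0.001, the smallest that 1000 placements can give. There were 4 of 261 miRNA genes (against 1.43, adjusted permutation p = 0.09) and 0 of 20 rRNA genes (against 0.202, exact upper limit 16.8%). In the 485 IDR peaks of highest signal the excess was smaller for tRNA genes (7 genes, 3.99-fold) and larger for snRNA genes (7 genes, 18.4-fold). For tRNA genes it was 14.4-fold within 100 bp of a summit and 5.05-fold within 500 bp. With a distance of 500 bp, 10 miRNA genes were near a summit and the class passed the test (adjusted permutation p = 0.015).

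Peaks were unevenly spread over the chromosomes, compared with random placements over the nuclear genome. These placements do not allow for where promoters lie. Whether the spread of peaks goes beyond that of promoters was not tested. Chromosome III held 181 (18.7%, 95% exact CI 16.3 to 21.3, against 13.8% at random, adjusted permutation p = 0.0023) and chromosome V 140 (14.4%, 12.3 to 16.8, against 20.9%, adjusted permutation p = 0.0023). Chromosome I held 179 (18.5%, 16.06 to 21.04, against 15.01%, adjusted permutation p = 0.0052). That excess was not called without replicate 1 (17.4%, adjusted permutation p = 0.063) or in the 485 strongest peaks (16.5%, adjusted permutation p = 0.55). Chromosomes II (144, 14.8% against 15.2%), IV (163, 16.8% against 17.5%) and X (163, 16.8% against 17.6%) did not differ from random by the test. On the autosomes 485 of 807 peaks (60.1%, 56.6 to 63.5) lay in the central part, from 25% to 75% of the chromosome's length, against 44.5% to 55.2% in the random placements (adjusted permutation p = 0.0023).

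Sequence at the summits differed from sequence beside them. The GA repeat GAGAGAGA was within 50 bp of 9.38% of summits and in 1.19% of equal windows centred 300 bp away (adjusted exact p = 8.81e-17). CGCGAA was at 8.14% of summits and in 2.84% of flanks (adjusted exact p = 5.15e-07), and the Sp1-type site GGGCGG at 5.98% and 1.55% (adjusted exact p = 2.58e-06). Of the core sites that nuclear receptors are known to bind, AGGTCA was at 2.47% of summits and in 2.22% of flanks (adjusted exact p = 1) and AAGTCA at 2.78% and 4.28% (adjusted exact p = 0.11). RGTTCA (R is A or G) was rarer at summits, 4.95% against 9.95% (adjusted exact p = 5.72e-05). The GATA site TGATAA (2.06% against 9.38%, adjusted exact p = 2.27e-12), TATAAA (4.12% against 10.4%, adjusted exact p = 1.75e-07), the homeodomain site TAATTA (1.75% against 5.57%, adjusted exact p = 3.53e-04) and the splice acceptor TTTCAG (5.57% against 21.4%, adjusted exact p = 6.48e-24) were rarer too. CACGTG, CAGGTG, ATTGGT, TGACGTCA, TGACTCA and GTAAACA were not called. Tests were exact McNemar tests over 16 motifs with Benjamini-Hochberg adjustment. Each used 1 randomly drawn flank per peak, while the flank shares are means of both sides, so a call near the threshold can depend on the draw. CACGTG was only at the summit in 35 peaks and only in the drawn flank in 21 (adjusted exact p = 0.12). Its shares were 3.61% of summits and 1.75% of flanks. The summit windows had 47.02% G and C, the flanks 35.2% and the nuclear genome 35.4%. Against shuffled summit windows, which keep that composition, GGGCGG (adjusted exact p = 0.098), TAATTA (adjusted exact p = 0.14) and TTTCAG (5.57% against 4.69%, adjusted exact p = 0.76) were not called. CGCGAA (8.14% against 4.64%, ratio 1.76), TGATAA (2.06% against 4.64%, ratio 0.444) and TATAAA (4.12% against 6.75%, ratio 0.611) were still called, with smaller differences than against flanks. So was the nuclear receptor site RGTTCA, as rarer at summits (4.95% against 8.04%, ratio 0.615, adjusted exact p = 0.0083). Without replicate 1, TAATTA was not called (adjusted exact p = 0.062), while AAGTCA (adjusted exact p = 0.023) and ATTGGT (adjusted exact p = 0.019) were called as rarer at summits. Without replicate 2, CACGTG was called as more frequent there (adjusted exact p = 0.023).

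**Figure D4:**
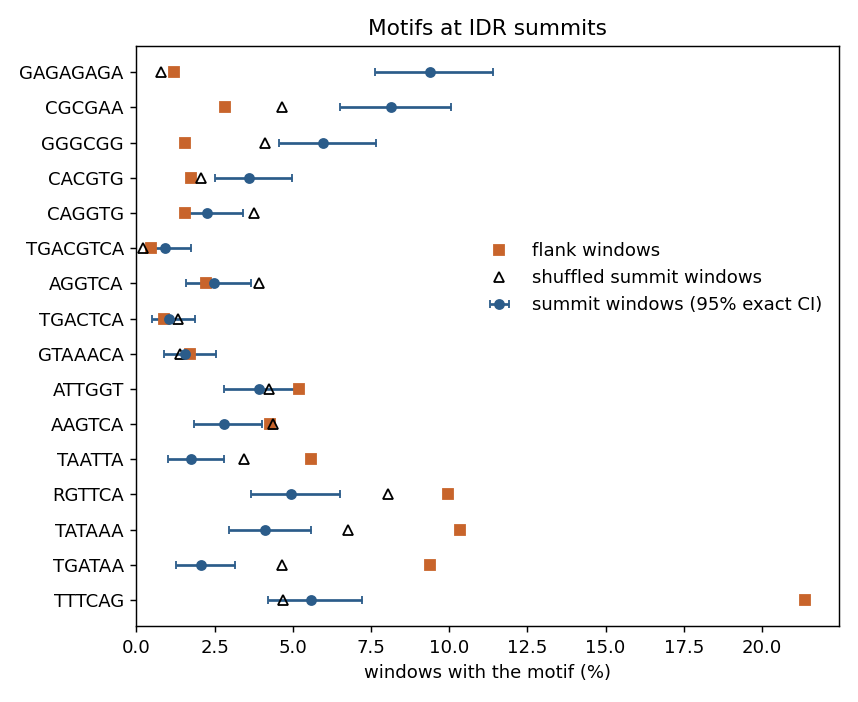
Share of windows with each motif (%) at the 970 IDR summits (points with 95% exact confidence intervals), in the flanks 300 bp away (squares) and in summit windows with shuffled bases (triangles). GAGAGAGA stands apart from both controls, at 9.38% against 1.19% and 0.773%, while TTTCAG is below its flanks and near its shuffled value.

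The locus of the tagged gene gave no region. The gene nhr-237 (WBGene00021610, V 1625189 to 1626820, minus strand) had none within 5000 bp in any of the 4 ce11 lists. Of all protein-coding genes 2.26% had none in every list. At unc-119 (WBGene00006843, III 10902641 to 10908935, plus strand), the marker gene of the strain, the replicate 1 list had 3 regions, the best of rank 1026 (III 10903399 to 10903758, signal 28.9). The replicate 2 list had 5, the best of rank 3832 (III 10911660 to 10912039, signal 16.97). The pooled list had 1, of rank 1750, and the IDR list had 0.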

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

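Of 458 comparisons of a result with an alternative, 435 were rated the same. For a result past the threshold this meant the same direction and side of it. A result not past it had only to stay so, and its direction could change. Counts of calls had only to stay close to the main count. In this part only the placements matched on GC content were chosen after the data were seen; they gave 25.3% of positions in promoters against 69.0% of summits (permutation p = 0.001). The promoter share was between 59.2% and 79.6% with other windows and past the test with each. The overlap of the 970 strongest regions of both replicates was lowest with summits within 100 bp (59.5%) and with lists of 1940 regions (52.8% and 53.9%), and past the test throughout. With shuffled bases in place of flanks, 3 motifs were less frequent at summits, against 5 with flanks. TTTCAG then turned to 0.876 percentage points more frequent at summits, which was not past the test. Shuffling keeps the G and C content, and the cause was not tested further. Among odds ratios of lists, 12 of 255 comparisons changed side of the threshold, among them F-box, proteasome and cell cycle genes as given with the results; aminoacyl-tRNA synthetases were called without replicate 2 (4.13), autophagy genes with the widest promoters (7.29) and collagens with nearest genes only (0). Using the middle of the region in place of its summit moved almost nothing, since they coincide in 97.01% of peaks, and says nothing about stability. No paired analysis was possible because there was 1 group. Read depth is unknown, so what it limits could not be stated.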

Other observations

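All tests in this part were chosen after the peaks had been seen, and for those on GC content, on noncoding RNA genes and on X matches of 10 bases the outcome each explanation predicts was written down before they were run. Among 118 families of at least 10 protein-coding genes with a common name stem, outside the fixed lists, 2 were bound more often and 0 less often (Fisher exact test, Benjamini-Hochberg adjusted over the 118). The sec genes, of which many act in protein translocation and secretion, had 6 of 19 promoters bound (odds ratio 9.50, 95% CI 2.95 to 26.9, adjusted Fisher p = 0.019), led by sec-61.G, sec-15, sec-3 and sec-61.B. The vps genes of vesicle sorting had 7 of 31 (6.01, 2.18 to 14.4, adjusted Fisher p = 0.027), led by vps-32.1, vps-60, vps-22 and vps-51. The rab genes had 5 of 19 (adjusted Fisher p = 0.057) and the mrpl genes of mitochondrial ribosomes 7 of 41 (adjusted Fisher p = 0.077), and neither was called.

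Summits on chromosome X were in promoters less often than those on autosomes, 86 of 163 (52.8%) against 583 of 807 (72.2%; Fisher exact p = 1.88e-06). Promoters cover 21.8% of X and 27.1% of the autosomes. The 970 strongest regions of replicate 2 gave 46.5% against 73.4% and those of replicate 1 gave 52.4% against 69.6%.

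The promoters of ribosomal protein genes and of 8 other lists were bound more often than those of other genes. GC content of the promoters was tested as a cause within 10 strata of the highest GC share around any base of the promoter (50 bp either side), and all 9 lists stayed past the threshold (Cochran-Mantel-Haenszel test, ribosomal odds ratio 29.6, 18.3 to 48.1, against 48.7 without strata), which argues against it as the whole cause. Of the 3 lists bound less often, F-box genes were not called within the strata (0.370, 0.154 to 0.893, adjusted p = 0.063 by the same test, which is not an exact one, against 0.319 without strata). Without the 61 summits within 250 bp of a tRNA, snoRNA or other noncoding RNA gene, all 9 lists again stayed past the threshold. That argues against noncoding RNA genes within this distance as the whole cause. Signal that a ChIP of any protein may give at active promoters stays open, because neither another factor nor an untagged control was analysed here; any of the 3 nuclear receptor core sites was at 9.69% of summits and in 15.9% of flanks, which decides nothing as the site of NHR-237 is not given in the sources used here, and no biological explanation was tested.

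Some of the strongest X peaks held a close match to TCGCGCAGGGAG, a sequence known from the sites where the dosage compensation complex is recruited to X: a match of at least 11 of the 12 bases was within 100 bp of the summit in 13 of 163 X peaks and 0 of 807 autosomal peaks, and in 5 of the 7 X peaks among the 15 strongest. Across the genome 17 of 32 such matches on X (53.1%, 95% exact CI 34.7 to 70.9) and 0 of 37 on autosomes were at a summit, but the 0 had been seen before the rest was counted. The 17 matches lay at the 13 peaks, of which those at X 2997022 to 2997177 and X 2997121 to 2997484 overlap. Neither matches nor peaks are therefore all independent, which the interval does not cover. Weaker matches of exactly 10 bases, more than 1000 bp from any closer one, had not been seen, and 7 of 242 on X (2.89%, 1.17 to 5.87) and 8 of 1322 on autosomes (0.605%, 0.262 to 1.19) were at a summit (Fisher exact p = 0.0041), which is consistent with binding at the recruitment sites as a hypothesis. The odds ratio was 4.88 with a 95% interval from 1.49 to 15.6, short of the lower bound of 2 set beforehand, so base composition of X stays open, as does open chromatin that any ChIP picks up, which was not tested. Peaks with a match of at least 11 bases were farther from a start site of a protein-coding gene (median 2650 bp against 679.5 bp for other X peaks, permutation p = 0.013) and stronger (median signal 260 against 73.1).

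The octamer AGACGCAG had the greatest excess at summits over flanks among 19297 octamers in the 504 peaks of chromosomes I, II and III. In the 466 peaks of chromosomes IV, V and X, which had been seen in an earlier search and so are not blind, it was at 15.7% of summits (95% exact CI 12.5 to 19.3) and in 0.322% of flanks (exact McNemar p = 2.12e-22). Multiplied by the 32896 possible octamers, since these peaks had been searched too, that p is 6.97e-18, which argues against a pick by chance among many, and 0.536% in shuffled summit windows argues against base composition. The octamer was at 12.1% of summits in promoters and 18.3% of other summits (Fisher exact p = 0.012), and at 14.7% and 10.8% of the 970 strongest regions of replicates 1 and 2. Which protein binds it stays open, and no biological explanation was tested.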
